A study of Rattus norvegicus with 12 samples.

How the data were processed

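Gene expression was measured in kidney cortex of male rats on 12 arrays of 1 type, each hybridised with biotin-labelled cRNA of 1 sample in 1 colour, per the labels' protocols. The arrays fall into 4 groups of 3: nondiabetic and diabetic rats at 10 weeks of age, and nondiabetic and diabetic rats at 20 weeks. The deposited values are linear probe-set signals (intensity) made with GCOS, the array maker's software, per the submitters' processing notes; its version, the summary method and the detection calls are not given in the sources used here. In the deposited table the mean signal of each array after trimming 2% at each end was 500.2 within rounding, so the authors had scaled the arrays to a common level, and the values were used as deposited. Scaling of this kind sets the typical signal of every array equal, so a shift of most transcripts in 1 direction could not be seen, and each difference is relative to the other transcripts on the array.

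The table held 31099 probe sets, of which 57 were control probe sets and were left out. Signals below 1 (424 values) were set to 1 before log2 was taken. The 40% of the remaining probe sets with the lowest mean log2 signal over the 12 arrays were left out, a limit at a geometric mean signal of 70.9, and 18625 were tested. Dim probe sets lie close to the background, so the sizes of their fold differences are uncertain. Gene names came from the array's annotation, updated through gene identifiers and synonyms of the RefSeq gene table, which was used for names alone: 20832 probe sets named 1 gene, 436 named several and 9831 named none here. No gene was named from a probe set with several. Of the probe sets tested, 13974 named 1 gene, covering 10583 genes.

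Differences were tested per probe set with limma 3.58.1 in R 4.3.3. A linear model with 4 group means was fitted to all 12 arrays (8 residual degrees of freedom), and the variances were moderated with eBayes with an intensity trend. There were 5 comparisons: diabetes at 10 weeks, diabetes at 20 weeks, the interaction (the diabetes difference at 10 weeks minus that at 20 weeks), age in nondiabetic rats (20 minus 10 weeks), and the mean diabetes difference over both ages. All tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all probe sets tested in a comparison. Log2 differences are given with the standard error (SE) of this model and signals as mean ± SD over 3 arrays. The precision is limited by the number of arrays. The arrays of the 10-week and of the 20-week comparison do not overlap, but both use the same pooled estimate of the variance.

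Lists of pathway genes (14) and of cell type markers (9), compiled from general knowledge, were tested with limma's camera with a preset inter-gene correlation of 0.01 and again with a correlation estimated from the data, on 1 probe set per gene (the brightest), with Benjamini-Hochberg adjustment over the 23 lists of a comparison. Beside them stand the members past 0.05 over all probe sets and those past it when adjusted over the list alone. The genes named in the text were set by a rule. Per comparison it takes the 10 largest higher and the 10 largest lower differences among called genes with a single symbol, with no overlap between the arrays of the groups where 2 groups were compared, 1 probe set per gene (the smallest p). Numbered loci are left out. Where fewer than 10 were called it takes the 10 smallest p-values. It adds the 4 members of each list with the smallest p. The design, the lists, this rule and most alternatives were fixed before the data were examined.

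The test was checked on simulated data of the size of the real set (18625 probe sets, 50 changed at each size). A log2 change of 1 was recovered for 50% at 10 weeks, 70% at 20 weeks, 38% in the interaction, 60% for age in nondiabetic rats and 84% over both ages, and between 3.17% and 4.96% of the calls were false. The comparisons at 10 and 20 weeks had the same median SE (0.184), so 50% and 70% differ through the random draw. At a change of 1.5 they gave 76% and 70%. The noise was drawn independently for each probe set, so the false share need not hold where probe sets vary together. Alternatives were other scalings between arrays (quantile, median), other filters on dim probe sets, an offset of 16 before log2, other estimates of the spread, array weights, fits of 2 groups, the replicate number as a block, each array left out in turn, and 2 settings chosen after the data were seen (the 3'/5' signal ratio as a covariate, and both doubted arrays left out). Same-group samples are numbered 1 to 3 in the labels, with no statement that a number marks a shared litter or day. The rats are described as littermates, and the labels do not tie an array to a rat, so the p-values measure the spread between these samples.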

Results

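Transcript signals were compared in renal cortex of diabetic and nondiabetic male rats whose diabetes began before or after puberty. Diabetes was induced with intravenous streptozocin, a toxin of the insulin-producing beta cells, at 65 mg/kg. The injection was given at 4 weeks of age in the younger rats and at 14 weeks in the older rats, and nondiabetic rats received vehicle. Pellets were implanted 3 days later, with insulin palmitate in diabetic rats, and tissue was taken after 6 weeks, at 10 and 20 weeks of age. The sample labels give the glucose of diabetic rats as 350 to 450 mg/dl, while the series description gives 350 at both ends of the range. No group had streptozocin without diabetes, and insulin pellets went with diabetes. Differences called those of diabetes can therefore include effects of both treatments. The label of 1 array, 10-week diabetic replicate 1, names a vehicle pellet. Each of the 4 groups had 3 arrays. Correlations between arrays lay between 0.941 and 0.976, and no pair of arrays was identical. The 3'/5' signal ratio of the Gapdh control, which rises as RNA degrades, was higher at 20 than at 10 weeks (log2 difference 0.20, exact permutation p = 0.013, 6 against 6 arrays). It was highest in 20-week nondiabetic replicate 1, at 2.09. This array and the one with the vehicle label are called the doubted arrays. Between diabetic and nondiabetic rats the Gapdh ratio differed by 0.019 on the log2 scale (exact permutation p = 0.879). The ratio of the beta-actin control was also higher at 20 weeks (log2 difference 0.36, exact permutation p = 0.037). It was 6.3 in 10-week diabetic replicate 1, the lowest, and 11.2 in 20-week nondiabetic replicate 1. In 20-week diabetic replicates 2 and 3 it was 11.4 and 10.0, so doubt about RNA quality is not limited to 1 array. Below, the 3'/5' ratio is that of Gapdh.

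The mean of the diabetes differences at the 2 ages was asked first, and "over both ages" refers to this mean. A change at 1 age alone can pass in it. Per2, for example, gave -0.13 ± 0.19 at 10 weeks and -1.43 ± 0.19 at 20 weeks. Baat, which joins bile acids to glycine or taurine, had the largest rise among the called genes with a single symbol, 10.2-fold (log2 3.35 ± 0.28 SE, adjusted p = 8.72e-05). Its signal went from 99.2 ± 8.85 (SD, n = 3) to 967 ± 516 at 10 weeks and from 99.9 ± 28.1 to 1256 ± 717 at 20 weeks. The nondiabetic means lie near the limit of 70.9 used for dim probe sets, so the sizes of its rises, here and at each age, are uncertain. Nrep, a small protein first described in regenerating neurons, had the largest fall among the called genes with a single symbol, 3.92-fold (log2 -1.97 ± 0.13, adjusted p = 2.1e-05). Its signal went from 9227 ± 992 to 2446 ± 616 at 10 weeks and from 5508 ± 907 to 1383 ± 308 at 20 weeks. In all, 833 of 18625 probe sets were called, 398 higher and 435 lower in diabetic rats, and they named 633 genes.

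Among the other genes that rose over both ages were the fibrinogen chains Fgb (log2 1.91 ± 0.45) and Fga (1.66 ± 0.21) and the tubular injury marker Havcr1 (1.68 ± 0.29). The enzymes Ftcd of histidine breakdown (1.58 ± 0.26) and Bhmt of homocysteine remethylation (1.5 ± 0.18) rose too. Stra6, a retinol transporter (1.46 ± 0.24), Adgrf1, an adhesion receptor (1.46 ± 0.38), Pdk4, an inhibitor of pyruvate dehydrogenase (1.44 ± 0.23), and Angptl4, an inhibitor of lipoprotein lipase (1.38 ± 0.23), rose as well. Another Pdk4 probe set gave -0.62 ± 0.51 and another of Fga 0.75 ± 0.22, and neither passed. The genes that fell included Hao1, the glycolate oxidase (-1.92 ± 0.25), the kallikrein Klk1c4 (-1.84 ± 0.42), whose near-identical relatives can share its probes, and Vwf, the clotting factor of endothelial cells (-1.78 ± 0.34). Tmem86a, a lysoplasmalogenase (-1.76 ± 0.11), the potassium channel subunit Kcne1 (-1.57 ± 0.26), Tcerg1l (-1.56 ± 0.28), Hspbap1 (-1.44 ± 0.20), Mpv17l (-1.36 ± 0.13) and the neurofilament Nefm (-1.26 ± 0.18) fell too. Some of these differences rest on dim signals, such as 35.7 to 88.4 for Fgb in nondiabetic rats, 49.6 to 85.1 for Havcr1 in nondiabetic rats of 10 weeks and 46.5 to 89.4 for Kcne1 in diabetic rats of 20 weeks, and their sizes are uncertain. The count was 525 without 10-week nondiabetic replicate 1, 544 without 10-week nondiabetic replicate 2, 553 without 10-week diabetic replicate 2 and 552 without 20-week diabetic replicate 3. It was 502 without an intensity trend in the variance and 490 without both doubted arrays.

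**Figure D1:**
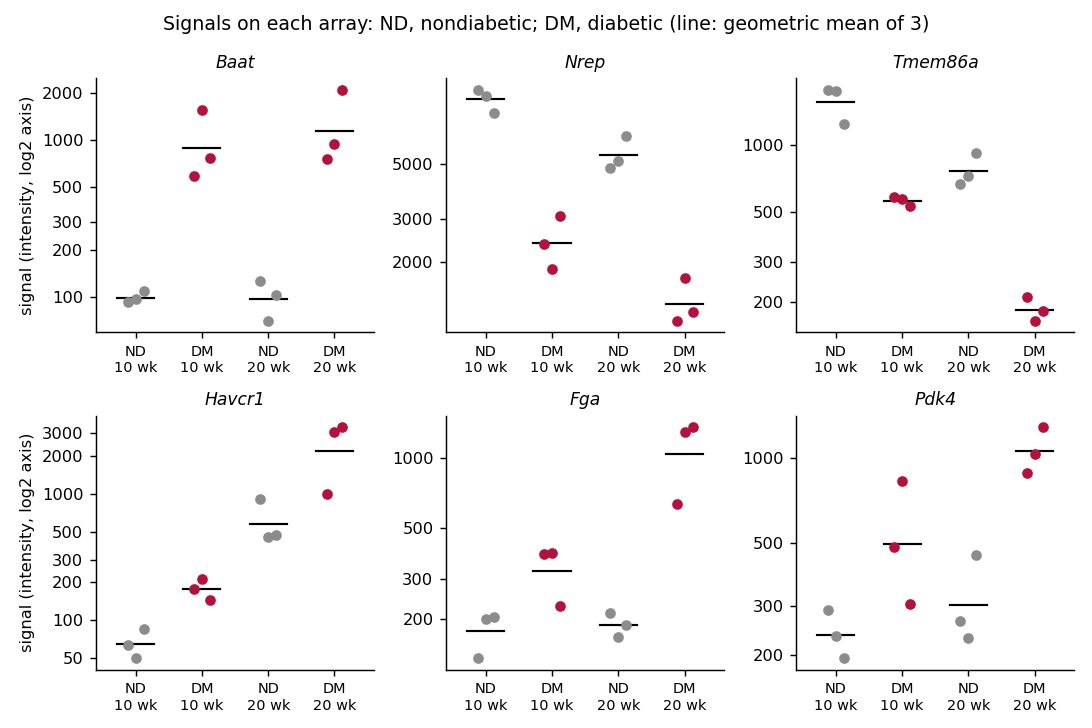
Signal (intensity, log2 axis) of 6 genes called over both ages on each of the 12 arrays; grey points are nondiabetic and red points diabetic rats, and lines are geometric means of 3 arrays. Baat lay between 70.3 and 126 on nondiabetic arrays and between 586 and 2076 on diabetic arrays.

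Of 42 measured genes of fatty acid oxidation and ketogenesis, 19 rose over both ages, none fell and 23 did not pass. Those that rose included Cyp4a1 (0.85 ± 0.14), a fatty acid hydroxylase, Eci1 (0.77 ± 0.13), an enoyl-CoA isomerase, and Plin2 (0.53 ± 0.07), which coats lipid droplets. With adjustment over the list alone, 22 were higher and 3 lower. The list's median was 0.32, with a camera adjusted p of 1.6e-09 and an adjusted p of 0.252 with an estimated correlation. As small a camera p came up in 5 of 100 splits of the arrays. The real grouping is included in this count, as in all counts of splits and regroupings below. Markers of fat, given below, were also called higher over both ages with the preset correlation. Of 29 genes of sterol and fatty acid synthesis, 6 fell, among them the desaturases Fads1 (-0.93 ± 0.14) and Fads2 (-0.50 ± 0.09) and the citrate lyase Acly (-0.48 ± 0.07), and 22 did not pass. When adjusted over the list alone, 12 were lower and 1 higher. Dhcr7, which makes the last step to cholesterol, rose instead (1.04 ± 0.17). The list's median was -0.23 (camera adjusted p = 9.14e-06; adjusted p = 0.264 with an estimated correlation). Of 30 tubular injury genes 9 rose and none fell. Besides Havcr1, Fga and Fgb they included Spp1, or osteopontin (1.15 ± 0.18), and S100a6 (0.56 ± 0.10), and 16 were higher when adjusted over the list alone. Counts of list members rest on the brightest probe set of each gene; of Cp, or ceruloplasmin, another probe set rose (0.82 ± 0.20). The list's median was 0.44 (camera adjusted p = 1.13e-09; adjusted p = 0.252 with an estimated correlation), and 13 of 100 splits of the arrays gave as small a camera p.

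Among 53 genes of antioxidant and xenobiotic defence, 7 rose, including the glutathione transferase Gsta3 (0.90 ± 0.13) and Txnip, a thioredoxin inhibitor (0.72 ± 0.11). The NADPH oxidase Nox4 (-0.74 ± 0.10) and its partner subunit Cyba (-0.41 ± 0.07) fell. The list had a median of 0.15, and 12 were higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.00447; adjusted p = 0.239 with an estimated correlation). Of 49 proximal tubule transport genes 6 rose, among them Slc2a2, the glucose transporter of the basolateral membrane (0.72 ± 0.12), Slc27a2 (0.51 ± 0.06), which takes up fatty acids, and Slc17a3 (0.53 ± 0.09). The amino acid transporter Slc7a7 (-0.55 ± 0.09) was 1 of 2 that fell, and 14 were higher and 4 lower when adjusted over the list alone. The list's median was 0.086 (camera adjusted p = 0.0427; adjusted p = 0.319 with an estimated correlation). This call was lost with quantile normalization (median 0.033, adjusted p = 0.488), the stricter filter on dim probe sets (0.028, adjusted p = 0.208), array weights (adjusted p = 0.0544) and the mean of all probe sets of a gene (0.050, adjusted p = 0.0741), and without both doubted arrays (0.039, adjusted p = 0.151). It was also lost without 10-week nondiabetic replicate 1 (median 0.016, adjusted p = 0.158), 10-week diabetic replicates 1 (0.031, adjusted p = 0.0621) or 2 (adjusted p = 0.105), 20-week nondiabetic replicates 1 (adjusted p = 0.117) or 2 (adjusted p = 0.0579) or 20-week diabetic replicate 1 (0.022, adjusted p = 0.0807). Of 15 markers of podocytes and the glomerulus 4 fell, namely Nphs1, or nephrin (-0.48 ± 0.10), Ptgds (-1.23 ± 0.28), Ptpro (-0.40 ± 0.10) and Dach1 (-0.36 ± 0.09). With adjustment over the list alone 8 were lower, and the median was -0.28 (camera adjusted p = 3.51e-04; adjusted p = 0.239 with an estimated correlation). Of 40 inflammation and leukocyte genes 2 rose, Icam1 (0.36 ± 0.08) and Csf1r (0.36 ± 0.09), and 3 were higher and 1 lower when adjusted over the list alone. The median was 0.25 (camera adjusted p = 0.016; adjusted p = 0.696 with an estimated correlation); without 20-week nondiabetic replicate 3 or 20-week diabetic replicate 2 that call was lost (adjusted p = 0.181 and 0.0724), as with the stricter filter (adjusted p = 0.0556), and without the first of these arrays the median was 0.16.

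**Figure D2:**
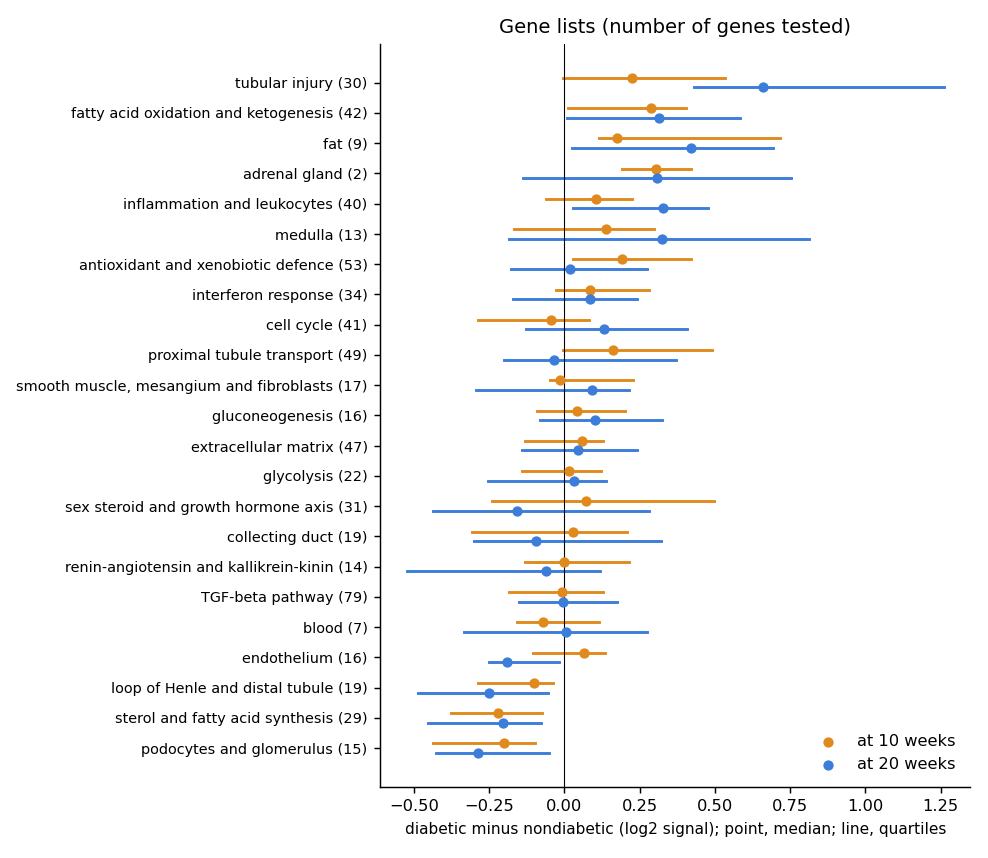
Median (point) and quartiles (line) of the log2 difference, diabetic minus nondiabetic, over the measured genes of 23 lists, at 10 weeks (orange) and 20 weeks (blue); the number of genes stands beside each name. The tubular injury list had a median of 0.22 at 10 weeks and 0.66 at 20 weeks, and the TGF-beta pathway list lay within 0.01 of 0 at both ages.

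At 10 weeks, after diabetes begun before puberty, 57 probe sets were called, 23 higher and 34 lower in diabetic rats, and 18 differed at least 2-fold. Baat rose 8.94-fold (log2 3.16 ± 0.39, adjusted p = 0.00714). Next came Akr1b8, an aldo-keto reductase (1.36 ± 0.24), Slco2a1, which carries prostaglandins (1.34 ± 0.22), Bhmt (1.34 ± 0.25) and the kinase Nek6 (1.26 ± 0.21). The chemokine Cxcl11 (2.38-fold), the sterol reductase Tm7sf2 (1.05 ± 0.18), Gsta3 (1.02 ± 0.19), Ccng1, a cyclin induced by p53 (0.93 ± 0.12), and the nuclease Dnase1 (0.92 ± 0.10) rose as well. Nrep fell by 1.94 on the log2 scale (SE 0.19, adjusted p = 0.00151), followed by Trib1 (-1.59 ± 0.26, with dim signals of 51.2 to 73.4 in diabetic rats), Nefm (-1.54 ± 0.26), Mlph (-1.47 ± 0.20), Tmem86a (-1.46 ± 0.16), Rpp25 (-1.05 ± 0.19), Tmem252 (-0.91 ± 0.17), Ablim3 (-0.87 ± 0.15), Cpm (-0.84 ± 0.16) and Tmem37 (-0.81 ± 0.12).

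Few members of the gene lists were called at 10 weeks. They were Gsta3, Slc27a2 (0.49 ± 0.08), the collecting duct water channel Aqp2 (0.68 ± 0.12), Krt7 (-0.62 ± 0.10) and Skil. Adjusted over the list alone, 13 of 42 fatty acid oxidation genes were higher and none lower, and the list's median was 0.29 (camera adjusted p = 6.33e-07; adjusted p = 0.392 with an estimated correlation). Of 53 antioxidant and xenobiotic defence genes 1 was higher and 1 lower when adjusted over the list alone, and the list's median of 0.19 had camera adjusted p = 3.65e-06 and adjusted p = 0.0489 with an estimated correlation. Sterol and fatty acid synthesis (median -0.22, adjusted p = 1.54e-04) and podocyte markers (median -0.20, adjusted p = 2.09e-04) were called lower, with adjusted p = 0.392 and 0.109 with an estimated correlation. Proximal tubule transport (median 0.16, adjusted p = 3.94e-04), fat markers (0.17, adjusted p = 0.0201) and tubular injury (0.22, adjusted p = 0.0201) were called higher, with adjusted p = 0.115, 0.297 and 0.924 with an estimated correlation. Adjusted over the list alone, 1 gene of the sterol and fatty acid synthesis list was higher and 4 lower. By the same adjustment 5 podocyte markers were lower, and 10 proximal tubule, 2 fat and 4 tubular injury genes were higher. Without 10-week nondiabetic replicate 1 the fat and tubular injury calls were lost (adjusted p = 0.0742 and 0.154), and proximal tubule transport lost its call with quantile normalization (adjusted p = 0.0548). Without that array the tubular injury median was 0.14 and the proximal tubule median 0.084; on it the signal of Mme, or neprilysin, was 532.5, against 2073 and 5206 in the other nondiabetic arrays of 10 weeks, and that of Slco1a1 44.8, against 722.5 and 2826.5. The podocyte median was -0.09 without 10-week diabetic replicate 1, the array with the vehicle label (adjusted p = 0.0122), or without both doubted arrays. The antioxidant median was 0.29 without 10-week nondiabetic replicate 3, and the fat median 0.27, 0.28 and 0.31 without 10-week nondiabetic replicates 2 and 3 and 10-week diabetic replicate 3, and 0.27 with quantile normalization. The fat call was also lost with the stricter filter on dim probe sets (median 0.27, adjusted p = 0.0958) and without both doubted arrays (adjusted p = 0.0575). Leaving out single arrays moved the count of 57 to 8, 5 and 115 (10-week nondiabetic replicates 1, 2 and 3), 11 and 15 (10-week diabetic replicates 1 and 2) or 32 (20-week diabetic replicate 2). Of the 115, 65 were higher and 50 lower, so the balance of directions turned. The count was 7 without an intensity trend, 9 with these 2 groups fitted alone and 10 without both doubted arrays.

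At 20 weeks, after diabetes begun past puberty, 529 probe sets were called, 228 higher and 301 lower, and 133 differed at least 2-fold. Baat rose 11.7-fold (log2 3.55 ± 0.39, adjusted p = 9.73e-04), Fga 5.49-fold (2.46 ± 0.30, adjusted p = 0.00153) and Fgb by 2.93 ± 0.64 on the log2 scale (adjusted p = 0.0309). Angptl4 (2.03 ± 0.33), Wfdc10a (1.93 ± 0.42), Havcr1 (1.92 ± 0.41), Pdk4 (1.80 ± 0.33), Stra6 (1.75 ± 0.38) and 1 probe set of the transcriptional repressor Zeb2 (1.68 ± 0.35) rose as well. The 3 other probe sets of Zeb2 gave 0.49 ± 0.19, 0.11 ± 0.29 and 0.87 ± 0.36, and another of Pdk4 0.04 ± 0.73, and none of them passed. Of 3 other Stra6 probe sets 1 passed (1.48 ± 0.34) and 2 did not (1.18 ± 0.35 and 0.92 ± 0.26), and the other Fga probe set passed (1.27 ± 0.30). One probe set of Tm9sf4 rose (1.99 ± 0.43), while the other 2 gave -0.09 ± 0.10 and -0.22 ± 0.10. Nondiabetic signals at 20 weeks were 41 to 72.2 for Fgb, 20 to 46.2 for Tm9sf4, 21.3 to 73.7 for Wfdc10a and 42.2 to 113.7 for Zeb2, and diabetic signals 57.5 to 80 for Klk1c4 and 45.1 to 86.7 for Tcerg1l. These lie near the limit of 70.9 used for dim probe sets, and no detection calls were given, so the sizes of these differences are uncertain. Hao1 fell 5.80-fold (-2.54 ± 0.35, adjusted p = 0.00292), followed by Klk1c4 (-2.52 ± 0.59), Tmem86a (-2.05 ± 0.16; another probe set gave -0.89 ± 0.25 and did not pass), Nrep (4.01-fold) and Vwf (-1.99 ± 0.49). Mpv17l (-1.87 ± 0.19), Tcerg1l (-1.80 ± 0.40), the retinol dehydrogenase Rdh16 (-1.77 ± 0.43), the thyroid hormone deiodinase Dio1 (-1.76 ± 0.26) and the anion exchanger Slc26a6 (-1.73 ± 0.30) fell as well.

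Of the 30 tubular injury genes none fell and 9 rose at 20 weeks, among them Myc (1.42 ± 0.24), Spp1 (1.34 ± 0.26) and S100a10 (0.86 ± 0.15), and 17 were higher when adjusted over the list alone; another probe set of Cp rose (1.42 ± 0.28). The list's median was 0.66 (camera adjusted p = 1.39e-13; adjusted p = 0.385 with an estimated correlation). Of 42 fatty acid oxidation genes 9 rose, with Angptl4, Pdk4, Cyp4a1 (1.08 ± 0.19) and Plin2 (0.75 ± 0.10) among them. Adjusted over the list alone, 20 were higher and 2 lower, and the median was 0.31 (camera adjusted p = 6.17e-08; adjusted p = 0.457 with an estimated correlation). In sterol and fatty acid synthesis 5 of 29 fell, including Fads1 (-1.22 ± 0.20), Acly (-0.58 ± 0.09) and Fasn (-0.59 ± 0.12), and 1 rose; another probe set of Me1 fell (-1.21 ± 0.27). With adjustment over the list alone, 7 were lower and 1 higher (median -0.20, camera adjusted p = 4.79e-04; adjusted p = 0.457 with an estimated correlation), and the median was -0.31 without 20-week diabetic replicate 1. None of the 40 inflammation and leukocyte genes passed, over all probe sets or over the list alone, at a list median of 0.33 (camera adjusted p = 0.00291; adjusted p = 0.522 with an estimated correlation). This call was lost without 20-week nondiabetic replicate 3 (median 0.12, adjusted p = 0.226) or 20-week diabetic replicate 2 (median 0.20, adjusted p = 0.0639). Podocyte markers had a median of -0.29, with none of 15 called and 4 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.0157; adjusted p = 0.457 with an estimated correlation). The count of 529 was 205 without 20-week nondiabetic replicate 2 and 312, 216 and 194 without 20-week diabetic replicates 1, 2 and 3. Of the 194, 53 were higher and 141 lower. The count was 191 without an intensity trend, 309 with these 2 groups fitted alone and 331 without both doubted arrays.

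Whether the effect of diabetes differed with age was the study's question. All of the 42 probe sets called at both ages went the same way, 19 higher and 23 lower, where independent lists of these lengths would share 0.282 and 0.549. Of the 529 called at 20 weeks, 458 (86.6%) had the same sign at 10 weeks, against 57.2% of all probe sets tested. Their median absolute log2 difference was 0.69 at 20 weeks, where they were selected, and 0.30 at 10 weeks. For the probe sets called at 10 weeks it was 0.77 at 10 weeks, where they were selected, and 0.80 at 20 weeks. Across all probe sets tested, which are not independent replicates, the log2 differences at the 2 ages had a Pearson correlation of 0.175. The overlap of 42 was 7 and 4 without 10-week nondiabetic replicates 1 and 2, 10 and 12 without 10-week diabetic replicates 1 and 2, 25 without 20-week nondiabetic replicate 1 and 22 without 20-week diabetic replicate 2 or 3. It was 4 without an intensity trend, 9 without both doubted arrays and 1 with unmoderated variances.

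**Figure D3:**
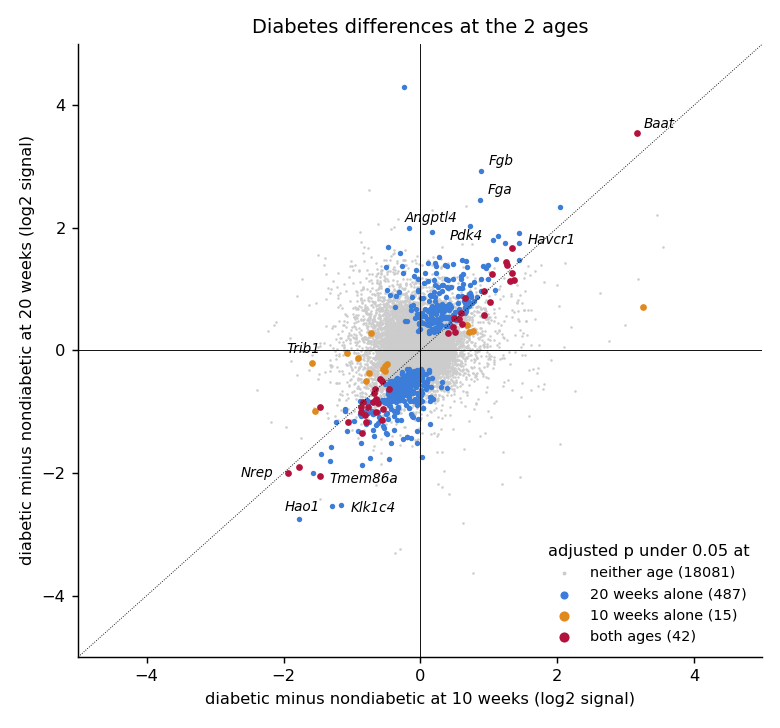
Log2 difference, diabetic minus nondiabetic, at 10 weeks (x axis) and 20 weeks (y axis) for the 18625 probe sets tested, coloured by the age at which limma's adjusted p was under 0.05; the dotted line marks equal differences. The 42 probe sets called at both ages, Baat and Nrep among them, lie in the quadrants of equal sign.

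In the interaction itself limma called no probe set (smallest adjusted p = 0.0979), and 1480 had an unadjusted p under 0.05, where chance alone gives about 931 on average. As many came up in 16 of 100 regroupings of the residuals of a model without an interaction. The median of the other regroupings was 993, so 1480 is not a clear excess. Of the 10 genes with the smallest p, Tnfrsf21, a death receptor, had a signal of 1296 ± 89.5 in nondiabetic and 1600 ± 60.6 in diabetic rats at 10 weeks, against 1928 ± 196 and 1265 ± 36.4 at 20 weeks (interaction 0.91 ± 0.13, adjusted p = 0.0979). Slc25a15, the mitochondrial ornithine carrier (1.0 ± 0.14), and Pter (1.21 ± 0.18) had the same adjusted p. Pter had 4943 ± 213 and 4347 ± 593 at 10 weeks and 4710 ± 896 and 1756 ± 99.5 at 20 weeks. Wsb1 (-1.01 ± 0.18), Zfp462 (-1.47 ± 0.28), Zswim6 (-0.96 ± 0.19) and Nit1 (-1.28 ± 0.26) had the opposite sign, while another Nit1 probe set gave 0.37 ± 0.20. Other probe sets of Slc25a15 gave 0.47 ± 0.11, 0.20 ± 0.40, 1.07 ± 0.31 and 0.87 ± 0.40, of Pter 0.39 ± 0.56 and of Zswim6 -1.92 ± 0.56 and -0.52 ± 0.18. The circadian clock genes Dbp (1.98 ± 0.36, adjusted p = 0.26), Bhlhe40 (0.91 ± 0.17, adjusted p = 0.269) and Per2 (1.30 ± 0.26, adjusted p = 0.38) completed the 10, and no label gave the hour of tissue collection. In simulated data a log2 interaction of 1 was recovered for 38% of changed probe sets. The interaction count was 2 without 20-week nondiabetic replicate 1 (Tnfrsf21 and Pter), 2 without 20-week nondiabetic replicate 3 and 3 with the 3'/5' ratio as a covariate (Tnfrsf21, Slc25a15 and Pter). It was 0 with unmoderated variances.

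**Figure D4:**
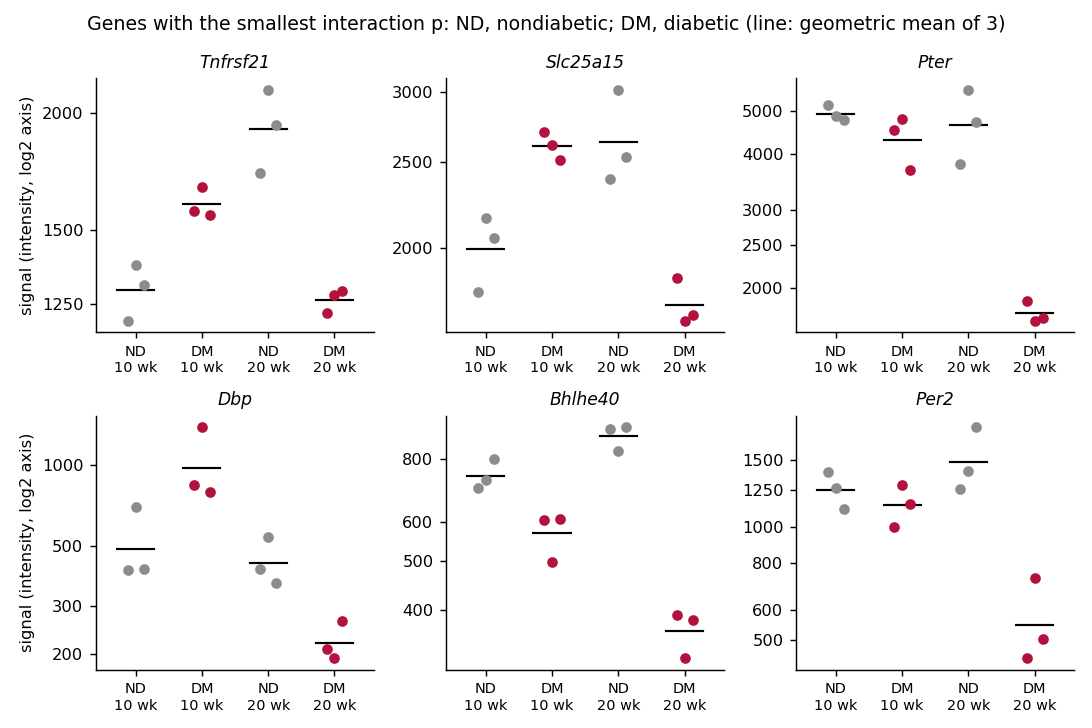
Signal (intensity, log2 axis) on each array of 6 of the 10 genes with the smallest interaction p; grey points are nondiabetic and red points diabetic rats, and lines are geometric means of 3 arrays. None passed the adjusted threshold; mean Dbp signals were 505 and 1005 in nondiabetic and diabetic rats at 10 weeks and 439 and 221 at 20 weeks.

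At the level of gene lists, tubular injury genes had a smaller diabetes difference at 10 than at 20 weeks (median interaction -0.43, camera adjusted p = 3.18e-08; adjusted p = 0.346 with an estimated correlation), with none of 30 called and 5 lower when adjusted over the list alone. As small a camera p came up in 4 of 100 regroupings, the real grouping included, and the median was -0.67 without 20-week diabetic replicate 1. The 4 other lists with a camera adjusted p under 0.05 were antioxidant and xenobiotic defence (median 0.18, adjusted p = 0.00573), endothelium (0.18, adjusted p = 0.0465), proximal tubule transport (0.13, adjusted p = 0.0465) and inflammation and leukocytes (-0.21, adjusted p = 0.0465). With an estimated correlation they had adjusted p = 0.346, 0.346, 0.36 and 0.907. None of their members was called, and 1 proximal tubule gene was higher when adjusted over the list alone. In 36 of 100 regroupings as many lists were called. Without 20-week nondiabetic replicate 1 the proximal tubule median was 0.19 and the inflammation median -0.36. The inflammation median was -0.05 without 20-week nondiabetic replicate 3 and -0.11 without 20-week diabetic replicate 2, and the endothelial median 0.12 without 10-week nondiabetic replicate 3. The proximal tubule call was lost without 10-week nondiabetic replicate 1 (adjusted p = 0.165), 10-week diabetic replicates 1 (0.0932) or 2 (0.233), 20-week nondiabetic replicates 2 (0.0522) or 3 (0.271) or 20-week diabetic replicates 2 (0.223) or 3 (0.0553). The inflammation call was lost without 10-week nondiabetic replicate 3 (adjusted p = 0.192), 10-week diabetic replicate 2 (0.173), 20-week nondiabetic replicates 2 (0.0563) or 3 (0.694) or 20-week diabetic replicates 2 (0.356) or 3 (0.0553). The endothelial call was lost without 10-week nondiabetic replicates 2 (adjusted p = 0.0547) or 3 (0.192), 10-week diabetic replicate 2 (0.19), 20-week nondiabetic replicates 1 (0.119) or 2 (0.0582) or 20-week diabetic replicates 1 (0.0608) or 3 (0.118). These 3 calls were also lost with quantile normalization (adjusted p = 0.0757 to 0.111), without an intensity trend (0.062), with array weights (0.0722 to 0.0775) and with the mean of all probe sets of a gene (0.0914 to 0.121). The proximal tubule and endothelial calls were lost with median centring (adjusted p = 0.0611 and 0.0542) and the stricter filter on dim probe sets (0.203 and 0.0922), the endothelial call without both doubted arrays (0.0587), and the inflammation call with no filter (0.202).

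The study looked at the TGF-beta pathway in particular. Of 108 pathway genes listed from general knowledge, 79 were tested. Skil, a repressor of SMAD signalling, fell at both ages (-0.46 ± 0.08 at 10 weeks, adjusted p = 0.0409, and -0.64 ± 0.08 at 20 weeks, adjusted p = 0.00207) and was the single member called at 10 weeks. At 20 weeks Myc (1.42 ± 0.24, adjusted p = 0.00945) and Ccn2, or connective tissue growth factor (0.67 ± 0.16, adjusted p = 0.0421), rose. At 10 weeks these 2 genes gave 0.11 and -0.07 and did not pass. Beside the probe sets counted, another of Jun fell at 20 weeks (-0.48 ± 0.12). Over both ages 4 members rose, among them the cell cycle inhibitor Cdkn1a (0.75 ± 0.16) and Myc (0.76 ± 0.17), and 2 fell, Skil and Cul1 (-0.24 ± 0.05). No member was called in the interaction, over all probe sets or over the list alone. Adjusted over the list alone, 1 was higher and 4 lower at 10 weeks, and 2 higher and 1 lower at 20 weeks. The list as a whole was not called: its median was -0.0074 at 10 weeks (camera adjusted p = 0.514) and -0.0019 in the interaction (adjusted p = 0.508). It was -0.0057 at 20 weeks, where the mean of 0.048 and the test had the opposite sign (adjusted p = 0.884), and -0.019 over both ages, where the mean of 0.0049 had the opposite sign (adjusted p = 0.888). Over both ages 5 were higher and 3 lower when adjusted over the list alone. Of 47 extracellular matrix genes, 2 rose and 2 fell at 20 weeks, Spp1 and Fn1, or fibronectin (0.73 ± 0.17), against Tgm2 (-0.99 ± 0.24) and P4ha1 (-0.43 ± 0.10); another probe set of Ogn, or osteoglycin, rose (1.14 ± 0.27). None passed at 10 weeks. Adjusted over the list alone, 4 were higher and 6 lower at 20 weeks and 2 higher and 1 lower at 10 weeks. That list was not called at 10 weeks (camera adjusted p = 0.952) or 20 weeks (adjusted p = 0.848), or over both ages (adjusted p = 0.917), where 4 rose and 2 fell, and 4 were higher and 7 lower when adjusted over the list alone.

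Nondiabetic rats of 20 weeks were compared with those of 10 weeks. The 3'/5' ratio also differed with age, so the differences cannot be put down to maturation alone. No probe set was called with limma (smallest adjusted p = 0.0739), and 1603 had an unadjusted p under 0.05. Havcr1 had the smallest p, with a signal of 66.1 ± 17.9 at 10 weeks and 608 ± 254 at 20 weeks (log2 3.16 ± 0.41, adjusted p = 0.0739), followed by Tnfrsf21 (0.63 ± 0.09, adjusted p = 0.098) and Tmem86a (-1.02 ± 0.16, adjusted p = 0.131). Cyp51 of cholesterol synthesis (-0.76 ± 0.13), the calcium-binding protein Calb1 (-0.79 ± 0.15), Endog (-1.19 ± 0.22), Spp1 (1.36 ± 0.26), Abhd3 (0.98 ± 0.18), Mgll (0.64 ± 0.12) and Pcbd2 (0.63 ± 0.13) came next, with adjusted p-values from 0.19 to 0.3. Other probe sets of Abhd3, Cyp51 and Pcbd2 gave -0.03 ± 0.36, -0.32 ± 0.26 and 0.13 ± 0.09, and the 2 others of Mgll 0.59 ± 0.19 and -0.28 ± 0.43. Cell cycle genes had a median of -0.28 at 20 against 10 weeks (camera adjusted p = 6.17e-08; adjusted p = 0.376 with an estimated correlation), with none of 41 called and 2 lower when adjusted over the list alone. With the stricter filter on dim probe sets their median was -0.09 (adjusted p = 0.0103), and with the 3'/5' ratio as a covariate -0.40. Of 47 extracellular matrix genes 1 was higher and 3 lower when adjusted over the list alone, with a median of -0.16 (adjusted p = 3.94e-04; adjusted p = 0.573 with an estimated correlation). That call was lost without 20-week nondiabetic replicate 3 (adjusted p = 0.0754), and the median was -0.29 without 20-week nondiabetic replicate 1 or both doubted arrays and -0.26 with the 3'/5' ratio as a covariate. Of 30 tubular injury genes 2 were higher when adjusted over the list alone, with a median of 0.12 and a mean of 0.54 (adjusted p = 0.00258; adjusted p = 0.573 with an estimated correlation). Among them Hmox1, or heme oxygenase, had signals of 15053 and 13593 in 20-week nondiabetic replicates 1 and 2 and 254 in replicate 3, against 188 to 229 in 10-week nondiabetic rats (log2 4.19 ± 1.38, adjusted p = 0.49). The 20-week nondiabetic arrays are also the baseline of the diabetes comparison at 20 weeks. The 3'/5' ratio moved with age, and with it as a covariate the tubular injury median was -0.054, the test's direction still being up (adjusted p = 0.481). Without 20-week nondiabetic replicate 1 the median was 0.0081 and the adjusted p 0.219 (0.206 without both doubted arrays), and without 10-week or 20-week nondiabetic replicate 3 the medians were 0.21 and 0.27. Interferon response (median -0.13, adjusted p = 0.0108), antioxidant and xenobiotic defence (0.085, adjusted p = 0.0141), podocyte (-0.15, adjusted p = 0.029) and collecting duct lists (-0.098, adjusted p = 0.0484) had adjusted p = 0.573, 0.376, 0.457 and 0.573 with an estimated correlation, and no member passed, over all probe sets or over the list alone. Each lost its call without 20-week nondiabetic replicate 3 (adjusted p = 0.142, 0.09, 0.0754 and 0.09). The interferon call was also lost without 10-week nondiabetic replicate 3 (adjusted p = 0.0935) or 20-week nondiabetic replicate 2 (0.13), and the antioxidant call without 10-week nondiabetic replicate 1 (0.109). The interferon median was -0.0079 without 10-week nondiabetic replicate 3, -0.059 and -0.069 without 20-week nondiabetic replicates 2 and 3, and -0.22 without 20-week nondiabetic replicate 1, without both doubted arrays or with the covariate. The antioxidant median was 0.052 and 0.13 without 10-week nondiabetic replicates 1 and 3. The podocyte call was lost without 10-week nondiabetic replicates 2 (adjusted p = 0.0535) or 3 (0.0704) or 20-week nondiabetic replicate 1 (0.0598, median -0.090, as without both doubted arrays), with the mean of all probe sets of a gene (0.0523) and with the covariate (0.069). The collecting duct call was lost without 10-week nondiabetic replicate 1 (median -0.0082, adjusted p = 0.488), 20-week nondiabetic replicate 1 (0.131) or 20-week diabetic replicate 1 (0.0552), and with the covariate (0.141). It was also lost with median centring (adjusted p = 0.0533), the stricter filter (0.0989), array weights (0.0674) and the mean of all probe sets of a gene (0.266), without an intensity trend (0.0664) and without both doubted arrays (0.0687). The count of 0 became 9 without 10-week nondiabetic replicate 3, 9 without 20-week nondiabetic replicate 3 and 2 without 20-week diabetic replicate 1, and it was 0 with unmoderated variances.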

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

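All 4 tests of the larger differences at 20 weeks were chosen after the results had been seen, and the test against equal changes was first run one-sided (the direction having come from the data) and is given two-sided. Splits for single gene lists were added after those lists' p-values had been seen, the tubular injury list being picked for the smallest interaction p of the 23; the splits by numbers of probe sets or of called lists were planned. The interaction test with a preset correlation set 5 gene lists apart between the ages, and none with an estimated correlation (smallest adjusted p = 0.346). Tubular injury genes had a median interaction of -0.43, antioxidant and xenobiotic defence genes 0.18, endothelial markers 0.18, proximal tubule transport genes 0.13, and inflammation and leukocyte genes -0.21, as log2 diabetes difference at 10 minus that at 20 weeks. As many lists were called in 36 of 100 regroupings of the residuals of a model without an interaction, with up to 12 lists, so chance cannot be excluded for the number of 5. Likewise 16 of 100 regroupings gave as many probe sets at an unadjusted p under 0.05, up to 2625 against the real 1480. For the tubular injury list alone, which was singled out for its small p, 4 of 100 regroupings gave as small a camera p (real 1.38e-09, smallest other 1.71e-12), a share under 0.05 that takes no account of the choice of this list among 23.

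The differences made by diabetes were larger at 20 than at 10 weeks by several measures: 529 against 57 probe sets, and 71.3% of the probe sets called over both ages had the larger absolute difference at 20 weeks (median 0.56 against 0.42). With the 3'/5' ratio as a covariate, 509 probe sets at 20 weeks and 42 at 10 weeks were called. That ratio hardly differed between diabetic and nondiabetic rats at 20 weeks (log2 difference 0.014), so the covariate could move the count little. RNA degradation as the cause of the higher count was therefore not decided, and the beta-actin ratio was not tried. A single array behind the higher count is argued against: the lowest count at 20 weeks with 1 array left out was 194, above the highest at 10 weeks of 115. With the preset correlation the tubular injury list kept a median interaction of at most -0.32 and a camera adjusted p of at most 1.56e-05. With an estimated correlation its interaction was not called (camera adjusted p = 0.346). Equal changes at both ages remain a candidate explanation, since 6 of 100 regroupings of the residuals gave a percent as far from 50, up to 78.4%. Age at onset, puberty included, stays open as an untested biological explanation.

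Other splits of the arrays were counted for the main results. Over both ages, 1 of 100 splits within each age, the real one, gave as many probe sets (833, against at most 21 in the others). This share lies under 0.05 and argues against chance for the count. Splits that mix diabetic and nondiabetic arrays in a group have a wider spread and so lower counts. The gap between 833 and 21 therefore does not measure how unlikely chance is. At 10 weeks (57, highest other 1), at 20 weeks (529, highest other 3) and for age in nondiabetic rats at an unadjusted p under 0.05 (1603, highest other 1936; 3 of 10 splits gave as many) the 10 splits are too few for a share under 0.05. For gene lists over both ages with the preset correlation, 4 of 100 splits gave as many called lists as the real 9. The highest other was 10 and the median of the others 4. This share lies under 0.05 but close to it, and the splits were a random draw, so chance is not firmly excluded for their number. With an estimated correlation none of the 23 lists was called (smallest camera adjusted p = 0.239). The tubular injury list reached its camera p (4.9e-11) in 13 of 100 splits, the smallest other being 2.84e-13, and the fatty acid oxidation list (1.39e-10) in 5 of 100, the smallest other being 4.07e-14, so chance was not excluded for either list as a whole. In the other 99 splits the camera p of these 2 lists was under 0.05 in 55 and 50. Such splits can keep part of the diabetes difference, so these counts do not show how far the genes of a list move together. The correlations estimated for the 2 lists were 0.265 and 0.257, against the preset 0.01.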

How the results depend on the processing

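The 3'/5' ratio as a covariate and the fit without both doubted arrays were chosen after the data were seen; all other settings were planned. The counts at 10 weeks (57), at 20 weeks (529) and over both ages (833) were 7, 191 and 502 without an intensity trend, 3, 194 and 479 by unmoderated 2-way ANOVA contrasts, and 10, 331 and 490 without both doubted arrays; with the 2 groups fitted alone, 10 and 20 weeks gave 9 and 309. The interaction count of 0 became 3 with the 3'/5' ratio as a covariate. The cause was not tested; the fits with fewer arrays have fewer degrees of freedom. With 1 array left out the counts ranged from 5 to 115 at 10 weeks, 194 to 520 at 20 weeks, 525 to 823 over both ages, 0 to 2 in the interaction and 0 to 9 for age in nondiabetic rats; where a group was left with 2 arrays, their spread was pooled with that of the others. In the remaining settings, the replicate block apart, these counts stayed within 1.5 times. Scaling to a common trimmed mean moved nothing, since the arrays had been scaled so, and says nothing about stability.

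The replicate block gave 32 probe sets at 10 weeks and 22 in place of the 42 called at both ages; the counts at 20 weeks (431), over both ages (728), in the interaction (0) and for age (0) stayed within 1.5 times. It ended the calls of the proximal tubule and endothelial lists in the interaction (both adjusted p = 0.0651). Whether the numbers pair the samples stays open. Correlations of same-numbered deviations ranged from -0.151 to 0.149, 4 of 18 pairs lay above 0.1, and 7 of 12 arrays correlated best with their own number. Same-numbered nondiabetic and diabetic arrays gave 0.022, 0.149 and 0.130 at 10 weeks and -0.043, 0.061 and 0.141 at 20 weeks. The block used each number across both ages, so a pairing within an age was not fitted.

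Of the named called genes, 0 of 24 at 10 weeks, 14 of 51 at 20 weeks and 41 of 68 over both ages kept their call under every setting, and none reversed. Of 33 calls of gene lists 32 were lost with an estimated correlation, up to 10 with 1 array left out and up to 8 in other settings. For the uncalled TGF-beta list the direction of the camera test, not the sign of the median, reversed at 20 weeks without both doubted arrays (median -0.017) and without 20-week diabetic replicate 3 (-0.0056), and over both ages with no filter on dim probe sets (-0.030) and without 20-week diabetic replicate 1 (-0.025). With 1 array left out the medians were -0.037 to 0.014 at 20 weeks and -0.039 to -0.0020 over both ages. Over the arrays left out its median ranged from -0.035 to 7.04e-05 at 10 weeks and from -0.060 to 0.025 in the interaction. Uncalled genes that reversed were Th at 10 weeks (0.08 as reported, -0.065 without both doubted arrays, -0.13 to 0.46 over the arrays left out), for age (-0.15 to 0.74) and over both ages (-0.44 to 0.0281), and Cidec in the interaction (-0.40 to 3.09). The gene list tests have no unmoderated form and were not run with that setting. Signals near the background, below the filter at a geometric mean of 70.9, limit what can be said of weakly expressed genes.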

Other observations

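The tests of clock genes and p53 targets were set after single members had been seen in the results. They were run on members not looked at singly before, which can vary together with those seen on the same arrays. Of these, the p53 targets Ephx1 and Gdf15 had been members of gene lists tested above. The splits for both groups were added later still, and the rule that a p53 response needs both a small camera p and a rare split was set after that camera p had been seen. Single members of further groups changed over both ages. In the growth hormone axis, Igfbp4 (-0.95 ± 0.16) and Igfbp5 (-0.39 ± 0.07), which bind insulin-like growth factors, fell, as did Igfals (-0.58 ± 0.12). The 3 other probe sets of Igfbp5 gave -0.35, -0.58 and -0.94 over both ages and did not pass, and at single ages 2 of them had the opposite sign (0.25 ± 0.43 at 10 weeks, 0.41 ± 0.40 at 20 weeks). Of the 31 genes of the sex steroid and growth hormone list 2 rose and 4 fell (camera adjusted p = 0.917), and another probe set of Igf1 fell (-1.17 ± 0.26). Collecting duct markers went both ways: of 19, 3 rose, among them Aqp2 (0.55 ± 0.09) and the sodium pump regulator Fxyd4 (0.78 ± 0.15), and 4 fell, among them Kcne1 and the anion exchanger Slc26a4 (-0.51 ± 0.10) of intercalated cells (adjusted p = 0.893). Of 13 medulla genes the osmolyte transporter Slc5a3 (0.78 ± 0.20) and Aqp4 (1.14 ± 0.23) rose and Krt7 (-0.74 ± 0.07) fell (adjusted p = 0.468). The median, mean and test differed in sign for the sex steroid, collecting duct, glycolysis and blood lists. In the renin-angiotensin and kallikrein list Hsd11b2, which inactivates glucocorticoids (-0.62 ± 0.13), and Klk1 (-0.44 ± 0.10) fell among 14 genes (adjusted p = 0.522), as did another probe set of Agtr1a (-0.50 ± 0.13).

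In glycolysis Ldha rose (0.46 ± 0.07) and Eno1 fell (-0.45 ± 0.05) among 22 genes (camera adjusted p = 0.893), and in gluconeogenesis Gpd1 rose (0.39 ± 0.07), the single call among 16 (adjusted p = 0.434). The interferon list had Tap2 higher (0.64 ± 0.15) and Irf3 lower (-0.23 ± 0.06) among 34 (adjusted p = 0.198), and none of 41 cell cycle genes passed on its brightest probe set (adjusted p = 0.522), while of cyclin Ccnd1 another probe set rose (0.67 ± 0.11). Loop of Henle and distal tubule markers had a median of -0.18, with Cldn10 (-0.50 ± 0.10) called among 19 (adjusted p = 0.0414; adjusted p = 0.38 with an estimated correlation), and of -0.10 without 10-week diabetic replicate 1. That call was lost without 10-week nondiabetic replicate 3 (adjusted p = 0.103), 10-week diabetic replicate 1 (0.0621), 20-week nondiabetic replicates 2 (0.106) or 3 (0.0679) or 20-week diabetic replicates 2 (0.0945) or 3 (0.078), as with no filter on dim probe sets (0.215), the stricter filter (0.0556) and the mean of all probe sets of a gene (0.0702). Fat markers had a median of 0.32, with Dgat2 (0.60 ± 0.15) called among 9 (adjusted p = 0.0209; adjusted p = 0.252 with an estimated correlation). With no filter on dim probe sets their median was 0.16, and with the stricter filter 0.20 (adjusted p = 0.292). Endothelial markers had Vwf as the single call among 16 (adjusted p = 0.522), and no marker passed of smooth muscle, mesangium and fibroblasts (17 tested, adjusted p = 0.893), blood (7, adjusted p = 0.893) or adrenal gland (2, adjusted p = 0.522).

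Clock genes stood among the smallest interaction p-values, and of those not looked at before, 6 driven through E-boxes (Per1, Nr1d1, Nr1d2, Bhlhe41, Tef and Hlf) had a median interaction of 0.71, and 4 that peak at the opposite phase (Bmal1, Npas2, Clock and Nfil3) one of -0.64 (exact permutation test over genes, which are not independent, p = 0.00476, 210 permutations). A difference between the arms as far from 0 as the real 1.36 was reached in 2 of 100 regroupings of the residuals (farthest other 1.46), a share under 0.05 that takes no account of the choice of clock genes for their small p, so chance stays open. A clock phase that differs between the groups is a candidate explanation, with Per1 as an exception (interaction -0.04): it rose over both ages (0.85 ± 0.12), while Bhlhe40 (-0.84 ± 0.09) and Per2 (-0.78 ± 0.13), also driven through E-boxes, fell. A single array behind the shift is argued against, since the difference stayed at or above 0.96 with each array left out. Whether the hour of tissue collection or an effect of diabetes at an age set the phase cannot be told apart, because no label gives the hour.

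Ccng1, Mgmt and Cdkn1a, targets of p53 or genes induced after alkylation of DNA, rose over both ages (0.95 ± 0.09, 0.75 ± 0.07 and 0.75 ± 0.16), which led to the hypothesis of a p53 response. Of 21 targets not looked at singly before 15 had a positive difference, with a median of 0.14, a camera p of 0.00279 and a p of 0.0113 with an estimated correlation. Among them 2 were called, Plk2 (0.95 ± 0.15) and Ephx1 (0.39 ± 0.10). Ephx1 had already been tested in the antioxidant and xenobiotic defence list and Gdf15 in the TGF-beta list, so the 21 were not wholly unseen. A median as far from 0 came up in 5 of 100 splits of the arrays (farthest other 0.16), so chance was not excluded and the hypothesis stays open. A single array behind the shift is argued against, as the median stayed at or above 0.10 with each array left out. Streptozocin, which alkylates DNA, and diabetes with its insulin pellets cannot be told apart as a cause, since no group had streptozocin without diabetes.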
